A study of Mus musculus with 2 samples.

How the data were processed

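Intestinal total RNA of male mice labelled gut-specific Gpcpd1 knockout or wild type was measured on 2 dual-colour Agilent mouse arrays of design 014868, both on one slide, so that no slide effect could be tested. Per the labels, RNA was extracted with QIAzol, copied into cRNA from a T7 primer and labelled with Cy3 or Cy5. The RNA labelled knockout carried Cy3 in replicate 1 and Cy5 in replicate 2. The labels give 20 weeks of age, and the series text a number of 5 mice; whether animals were pooled and whether the arrays share RNA extracts is not given in the sources used here.

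The authors' deposited scanner files hold, per the file headers, intensity values from Agilent Feature Extraction 11.5.1.1, as the mean pixel brightness of each spot in each channel and the median brightness of its local background, neither of them corrected. The submitters' processing notes name Feature Extraction 9.5 instead. Per the file headers, the processed intensity was background-subtracted, detrended over the array surface and dye-normalized by that software. The deposited log10 ratio column holds processed Cy5 over processed Cy3 of one array, and a deposited p-value column gives the software's error-model p that the ratio of one spot differs from 0. The deposited value table of the series holds the same log10 ratios rounded, with a largest difference of 5e-04, unturned for the dye swap, and with a column median of 0 in both arrays. It has 0 columns beyond those of the 2 arrays. Coordinates are those of the design file on mm9; no genome was used here.

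Each array had 43379 spots of gene probes, for 41174 probes, and 1639 control spots. Median intensity was 98.7 in Cy3 and 106 in Cy5 in replicate 1, and 103 and 105 in replicate 2, with a median local background of 26 and 44, and of 25 and 44. No spot was saturated. The software had put a surrogate value in place of a signal near background at 8124 and 7640 spots. Feature outlier marks covered 133 and 193 spots, and background marks 0 and 47. Over 245 probes printed 10 times each, the median SD of the log2 ratio was 0.183 in replicate 1 and 0.121 in replicate 2.

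Background was corrected with normexp and an offset of 50, and ratios were normalized by loess within each array with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Replicate 2 holds 13 spots with a local background over 200. When all spots entered the normexp fit, its Cy5 background mean there was -378, against -8.50 for Cy5 in replicate 1. The planned design left out spots marked as outliers without saying at which step. After these values had been seen, marked spots were left out before the normexp fit and loess, and the fit with all spots was added as an alternative. Log2 ratios of the spots of a probe were averaged and turned to knockout over wild type. A probe entered the tests when it was well above background for the same genotype on both arrays, which 29046 probes were. Symbols were updated through the transcript accession with a RefSeq table of GRCm38.p6, used for names only, for 31441 of the 43379 spots; the other spots kept the name in the file. For the 6847 genes with several tested probes the brightest was taken, which left 18987 genes or unnamed probes.

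The test was limma's lmFit and eBayes of the mean turned log2 ratio against 0, with 1 residual and 3.01 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. A dye term was left out, since it would use up the residual degree of freedom; the swap cancels a dye effect in the mean but leaves it in the spread. Besides this, genes at least 1.5-fold apart in the same genotype direction on both arrays were counted, next to those in the same dye direction. Gene lists were tested with limma's camera at a preset correlation of 0.01 over the 39 lists, each with 5 or more measured genes, and placed among 10000 random lists matched on intensity in 20 bins. Lists, tests and most alternatives were chosen before the data were examined. The lists cover choline and phospholipid pathways, lipid, sterol, bile acid, sugar and amino acid handling, drug metabolism, stress and clock genes, interferon, MHC class II and inflammation genes, respiratory chain and ribosome, and markers of gut cell types, gut regions and other tissues. The names in the text are Gpcpd1, the 12 genes higher and up to 12 lower with the largest value of the smaller of the arrays' ratios among those at least 1.5-fold apart on both and with a usual symbol (10 were lower), and up to 4 members per list by the same value. AK090125, Mt2, Slc30a1, Svs4 and the immunoglobulin segments fall outside this rule and were chosen after their values were seen. So were the list members Mzb1, Pou2af1, Derl3, Tnfrsf17, Jchain, Cd3e, Cd8a, Il17rb, Dclk1 and Ptgs1. The muscle genes Ckm, Acta1, Pvalb, Myh1, Tnnt3, Xirp2, Myoz1, Mb and Actn3 fall outside it too. Skeletal muscle, kidney and male gland lists were added after single genes had been seen; of the last, 3 genes were measured, too few to use.

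The procedure was tested on simulated data with the noise of this comparison over 18987 genes. limma recovered 0 of 50 genes changed 1.5-fold, 0 of 50 changed 2-fold, 22 of 50 changed 4-fold and 43 of 50 changed 8-fold, with 2 of 18787 unchanged genes called. The 1.5-fold rule took 5, 46, 50 and 50 of these 50, and 42 unchanged genes, whose noise was drawn from the real mean ratios and so holds real differences too. camera called 20 of 20 lists moved by 0.3, and 6 of 400 random lists had p under 0.05. Values were shuffled among genes here, which removes the correlation between members of a list. The simulation therefore cannot show whether the preset correlation suits the real lists. Alternatives were other background corrections, normalizations, filters, probe rules and spread models, the deposited value table, the error-model p and single arrays. Figures were drawn with matplotlib 3.10.9.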

Results

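Gene expression in the intestine was compared between mice labelled as lacking Gpcpd1 in the gut and mice labelled wild type. Gpcpd1 encodes GDE5, a phosphodiesterase that releases choline from glycerophosphocholine, and the comparison asks which transcripts differ in the gut when that enzyme is missing. The animals were males, 20 weeks old and fed a normal diet, and the series text gives a number of 5 mice without stating whether their RNA was pooled. Total RNA of both genotypes was hybridised together on 2 dual-colour Agilent arrays with 41174 different probes each. The dyes were swapped, so that the RNA labelled knockout carried Cy3 in replicate 1 and Cy5 in replicate 2. Spots well above background made up 75.3% of all spots for the RNA labelled knockout and 69.3% for the RNA labelled wild type in replicate 1, and 70.3% and 76.1% in replicate 2. All ratios below are log2 ratios of the RNA labelled knockout over the RNA labelled wild type, given as the mean ± SD of the 2 arrays (n = 2). The labels do not say whether the arrays share RNA extracts, so p-values measure the spread between 2 hybridisations, which may be technical, and the number of arrays limits the precision of every value.

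Gpcpd1 itself was not lower in the RNA labelled knockout. All 4 of its probes on the array were well above background in both genotypes. Probe A_52_P470017, the brightest (chromosome 2, 132355383 to 132355442, mm9), had a log2 ratio of 0.68 ± 0.56, with 0.28 in replicate 1 and 1.08 in replicate 2. Probe A_51_P464791, which overlaps it (132355405 to 132355464), was at 0.47 ± 0.25, and probe A_52_P384069 (132359834 to 132359893) at 0.62 ± 0.08. Probe A_52_P407755 (132390343 to 132390402) was at -0.13 ± 0.43 and differed in sign between the arrays. The gene was not called by limma (adjusted p = 1). The sources used here do not give the deleted part of the gene. A probe outside it need not change with the deletion, so it may check nothing about the labels. The ratios go against the label of the knocked-out gene at 3 of the 4 probes, so every direction below rests on the dye labels alone.

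**Figure D1:**
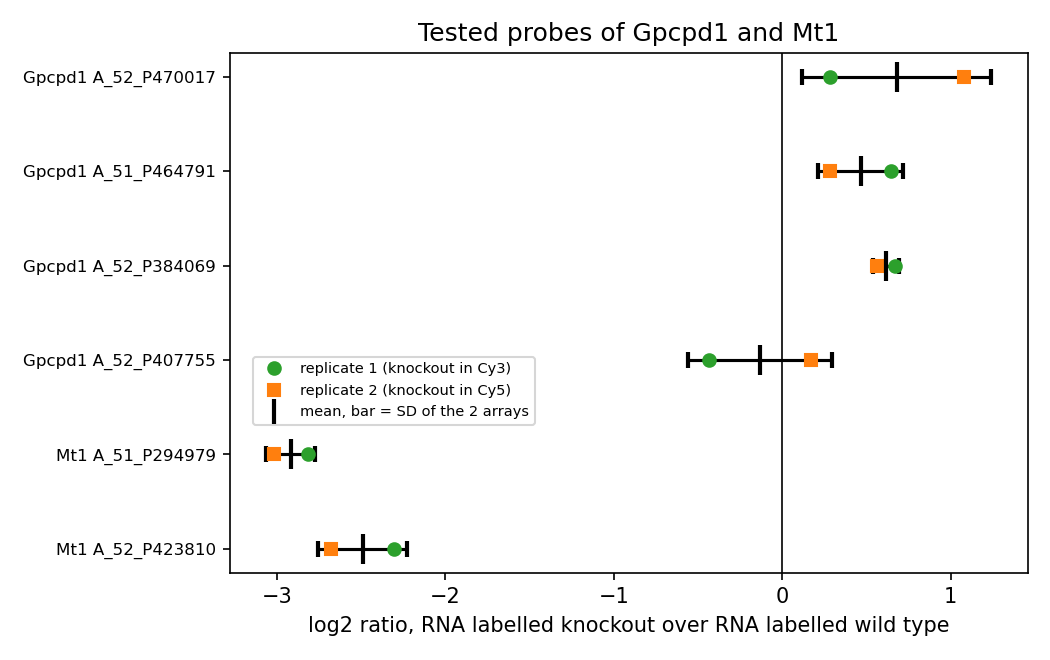
Log2 ratios of the RNA labelled knockout over the RNA labelled wild type (horizontal axis) for the 4 Gpcpd1 probes and the 2 Mt1 probes, one probe per line. Circles are replicate 1, squares replicate 2, and vertical marks with bars the mean and SD of the arrays; 3 Gpcpd1 probes lie above 0 on both arrays, and both Mt1 probes lie below -2 on both.

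Across the intestine, 41 of 18987 genes were at least 1.5-fold apart in the same genotype direction on both arrays, 30 higher and 11 lower in the RNA labelled knockout. Among the higher genes with a usual symbol, Myh4 and Myh8, heavy chains of fast and perinatal skeletal myosin, stood furthest apart. They were 4.55-fold and 4.28-fold higher (log2 ratios 2.18 ± 0.23 and 2.10 ± 0.02). The troponin subunits of fast muscle Tnnc2 (1.18 ± 0.62) and Tnni2 (0.90 ± 0.13) were 2.26-fold and 1.87-fold higher. Genes of the absorptive brush border and lipid handling were also among them. Plb1, a brush border phospholipase that also acts on lysophospholipids, was 3.81-fold higher (1.93 ± 0.30, chromosome 5, 32666473 to 32666532, mm9). Lct, the enzyme that splits lactose, was 2.67-fold higher (1.41 ± 0.61), and Fabp1, a cytosolic fatty acid binding protein, was 2.43-fold higher (1.28 ± 0.01, chromosome 6, 71154906 to 71154965, mm9). Ubd, a ubiquitin-like protein induced by interferon, was at 1.29 ± 0.55, and the interferon-inducible Igtp and Rsad2 were at 0.81 ± 0.04 and 0.77 ± 0.02. Kap, an androgen-regulated transcript named for the kidney, was at 1.42 ± 0.07, and Rgs13, a regulator of G-protein signalling, at 0.76 ± 0.01.

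Of the genes lower in the RNA labelled knockout and well above background in both genotypes, Mt1 stood furthest apart. This metallothionein, a small protein that binds zinc and copper, was 7.57-fold lower (-2.92 ± 0.14, chromosome 8, 96704011 to 96704070, mm9), and its second probe was at -2.49 ± 0.27. Tat, the liver enzyme that starts tyrosine breakdown, was 2.10-fold lower (-1.07 ± 0.10, chromosome 8, 112523207 to 112523266, mm9). Svs5, a secretory protein of the seminal vesicle, was not well above background in the RNA labelled knockout on either array and was at least 2.04-fold lower there; such bounds set the brighter group against the dim group's own signal, or against the lowest signal well above background where that is higher. The drug-metabolising cytochromes Cyp3a16 (-0.88 ± 0.22) and Cyp3a44 (-0.83 ± 0.01) were lower by 1.85-fold and 1.78-fold, and the galactosyltransferase B3galt5 (-0.92 ± 0.20) by 1.89-fold. Mal, a membrane raft protein, was at -0.81 ± 0.04. Mfsd2a, a carrier of lysophosphatidylcholine, was at -0.73 ± 0.06, the secreted phospholipase Pla2g5 at -0.72 ± 0.04, and the G-protein subunit Gna14 at -0.69 ± 0.14. Near-identical genes such as Cyp3a16 and Cyp3a44, or Myh4 and Myh8, can hybridise with each other's probes, so their values are uncertain one by one. Of the other probes of named genes, 3 of Myh8 and 2 of Plb1 were not well above background, and a further Plb1 probe was at 0.24 ± 0.04 (1.33 and 1.91 in the scanner software's processed ratios of the arrays). Both other Rsad2 probes were at 0.25 ± 0.03 and 0.28 ± 0.19, the second probe of Myh4 at 1.58 ± 0.34, of Cyp3a44 at -1.26 ± 0.29 and of Mal at -0.83 ± 0.07.

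No gene was called by limma at an adjusted p under 0.05 (smallest adjusted p = 0.452, shared by Mt1 and the clone AK090125). At an unadjusted p under 0.05 there were 236 genes, 184 higher and 52 lower, against 949 expected from uniform p-values. Genes at least 1.5-fold apart in the same dye direction, which the genotype cannot give, numbered 199, of which 196 had the brighter Cy3 signal. At 2-fold on both arrays the counts were 8 in a genotype direction and 0 in a dye direction, and at 1.3-fold they were 141 and 1321. The turned ratios of the arrays correlated at r = -0.38 across genes (Spearman -0.42, and genes are not independent replicates). The ratio of Cy5 over Cy3 also kept a trend over the array surface after loess. Its median log2 value in rows 1 to 67 was -0.18 in replicate 1 and -0.17 in replicate 2, against 0.08 and 0.05 in rows 201 to 266. With a surface over row and column taken off, chosen after the data were seen, 30 genes were at least 1.5-fold apart in a dye direction. There r was -0.21, and limma called 6 genes. With the scanner software's own processed ratios in place of normexp and loess, r was -0.02, limma called 38 genes (25 higher, 13 lower), 16 of them among the 41, and 159 genes were at least 1.5-fold apart in a genotype direction and 111 in a dye direction, of which 93 had the brighter Cy5 signal. Those 38 included Mt1, Svs5, Svs4 and Tat among the lower, and Plb1, Lct, Fabp1, Ubd and Kap among the higher. Muscle genes made up a large part of the higher: Myh4, Myh8, Myh1, Tnnc2, Tnnt3, Pvalb, Xirp2, Mb, Myoz1 and Actn3. Of these, Myh1, Pvalb and Xirp2 were not well above background in the RNA labelled wild type on either array. Mb, Myoz1 and Actn3 were well above background in it on only 1 array. With spots marked by the scanner software as outliers kept in the background fit, the count of 41 was 21.

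**Figure D2:**
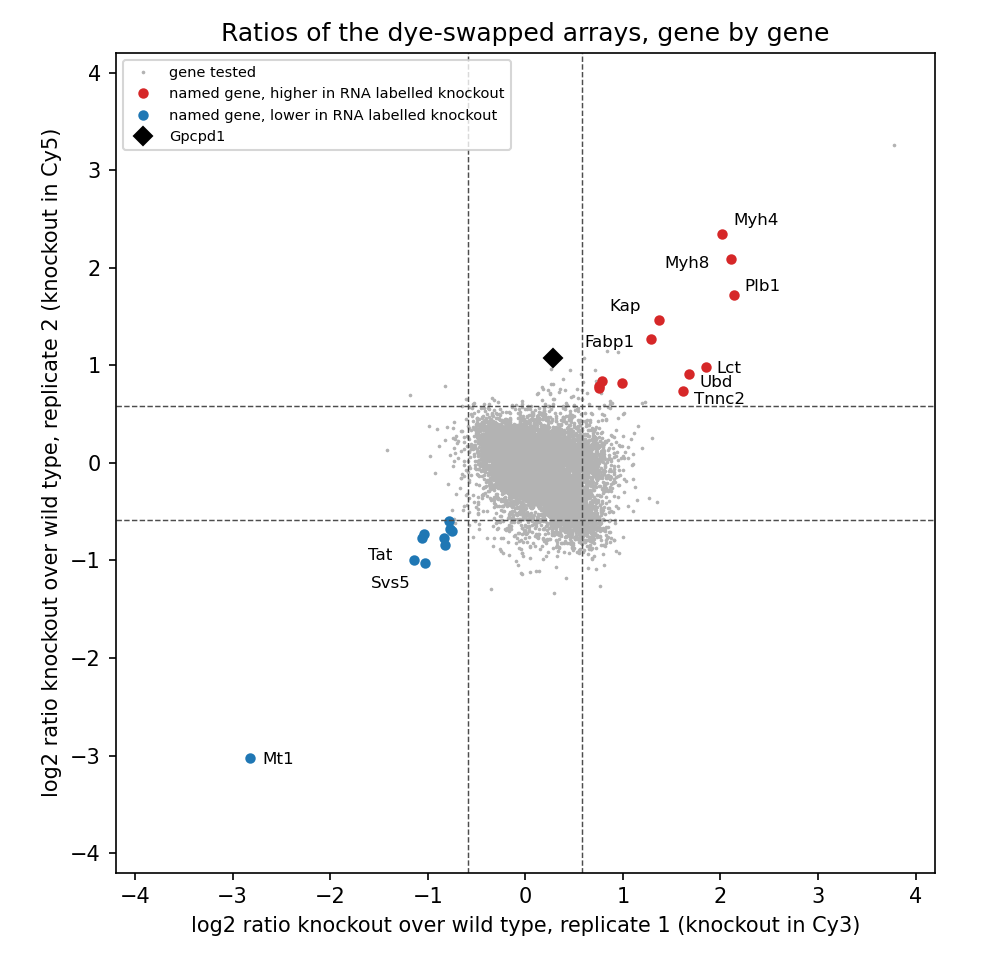
Log2 ratios of the RNA labelled knockout over the RNA labelled wild type in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for 18987 genes, with dashed lines at 1.5-fold. Red and blue points are the named genes higher or lower on both arrays, and the black diamond is Gpcpd1; the grey cloud leans from upper left to lower right (r = -0.38), and Mt1 and the Myh genes lie far from it along the other diagonal.

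Interferon-stimulated genes were the list with the largest shift. Of 29 measured members, 26 were higher in the RNA labelled knockout on both arrays, 6 of them by at least 1.5-fold on both, and none was lower on both. The list median was 0.44, with 0.54 in replicate 1 and 0.35 in replicate 2 (camera adjusted p = 1.91e-39 with the preset correlation, adjusted p = 0.605 with an estimated correlation). By the smaller of the arrays' ratios, the members furthest apart were Igtp, Rsad2, Oasl2 (0.83 ± 0.17), which is related to the oligoadenylate synthetases, and Ifi44 (0.67 ± 0.06). No member passed limma over all genes tested, and 10 passed when adjusted over the list alone.

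Lists of lymphocytes and antigen presentation were higher as well. Of 15 measured genes of B and plasma cells, 11 were higher on both arrays and none lower on both (median 0.27, with 0.44 in replicate 1 and 0.28 in replicate 2, camera adjusted p = 7.67e-11), with Fcmr, the receptor for IgM, at 0.93 ± 0.43, and Ms4a1, Cr2 and Cd22 at 0.67 ± 0.12, 0.40 ± 0.05 and 0.36 ± 0.02. The other 4 went opposite ways on the arrays: Mzb1 (0.17 ± 0.47), Pou2af1 (0.13 ± 1.02), Derl3 (0.10 ± 0.78) and Tnfrsf17 (-0.09 ± 0.18). Several of these are plasma cell genes, though Jchain, also of plasma cells, was higher on both at 0.27 ± 0.31. Of 18 genes of T and NK cells, 12 were higher on both (median 0.20, with 0.27 and 0.13, camera adjusted p = 4.51e-07), with Cd3g, a chain of the T cell receptor complex, at 0.52 ± 0.12, Cd3d at 0.33 ± 0.21, Cd8b1 at 0.26 ± 0.04 and the chemokine Xcl1 at 0.28 ± 0.02. The other 6 went opposite ways, among them Cd3e at -0.02 ± 0.24 and Cd8a at 0.10 ± 0.47. Of 10 genes of MHC class II, 6 were higher on both (median 0.27, with 0.36 and 0.22, camera adjusted p = 2.15e-06), with H2-Oa at 0.42 ± 0.24, the transactivator Ciita at 0.40 ± 0.29, H2-DMb2 at 0.30 ± 0.05 and H2-DMa at 0.26 ± 0.10. Of 11 genes of tuft cells, a chemosensory epithelial type, 7 were higher on both and 1 lower on both (median 0.21, with 0.42 and 0.10, camera adjusted p = 3.07e-05), with Rgs13 and Alox5ap at 0.76 ± 0.01 and 0.76 ± 0.35. Hpgds was at 0.35 ± 0.18 and Trpm5 at 0.28 ± 0.17. Il17rb was lower on both at -0.19 ± 0.09, while Dclk1 (0.21 ± 0.38) and Ptgs1 (-0.02 ± 0.10) went opposite ways. Markers of macrophages, granulocytes and mast cells did not pass (median -0.01, adjusted p = 0.943), with the eosinophil protein Prg2 at 0.25 ± 0.02 and Fcer1a at -0.16 ± 0.02. With an estimated correlation the adjusted p of these 4 shifted lists was 0.605.

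Genes around the pathway of GDE5 did not pass as a list. The 34 measured genes of glycerophosphodiester hydrolysis, choline uptake and phospholipid synthesis had a median of 0.03 (camera adjusted p = 0.0902), and 21 of them went opposite ways on the arrays. The list passed upward with normexp offset 0 (adjusted p = 0.0095) and with the outlier spots kept (adjusted p = 0.0485). Plb1 was the only member at least 1.5-fold apart on both, and choline kinase Chka was at 0.49 ± 0.36, Phospho1 at 0.21 ± 0.08 and Chpt1 at -0.14 ± 0.09. Genes of betaine synthesis, the methionine cycle and folate were lower by little (27 genes, 9 lower and 2 higher on both arrays, median -0.05, camera adjusted p = 0.0328), with the betaine-using methyltransferase Bhmt at -0.24 ± 0.10, Slc46a1 at -0.18 ± 0.07 and Shmt1 at -0.17 ± 0.05. Mthfd1l was higher on both at 0.38 ± 0.36. Lipid absorption and chylomicron genes passed in the upward direction with a median of 0.01 (32 genes, 11 higher and 4 lower on both arrays, adjusted p = 0.0119), with Fabp1 first, then Fabp2 at 0.70 ± 0.35, Dgat2 at 0.43 ± 0.29 and the lipid exporter Abca1 at 0.36 ± 0.06. Genes of sterol synthesis were lower (25 genes, median -0.05, adjusted p = 0.0186), 13 of them on both arrays, with Fdft1 at -0.33 ± 0.12, Insig1 at -0.31 ± 0.06 and Msmo1 at -0.24 ± 0.01. With the scanner software's processed ratios, the camera adjusted p of the betaine, lipid absorption and sterol lists was 0.104, 0.082 and 0.0668, at medians of -0.09, 0.03 and -0.12. Median centring turned the median of the lipid absorption list to -0.02, and the list did not pass camera (adjusted p = 0.065). With the outlier spots kept, the camera adjusted p was 0.109 for betaine and 0.135 for sterol genes, at a median of -0.06 for both. With an estimated correlation, the adjusted p of the 3 lists was 0.605, 0.638 and 0.605.

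Drug metabolism genes were lower (36 genes, 12 lower and 4 higher on both arrays and 20 opposite ways, median -0.05, camera adjusted p = 0.0067), with Cyp3a11 at -0.66 ± 0.11, Cyp3a25 at -0.42 ± 0.25 and the epoxide hydrolase Ephx2 at -0.37 ± 0.08, while Cyp3a13 was at 0.41 ± 0.29. Genes of inflammation and barrier defence were lower (27 genes, median -0.09, camera adjusted p = 0.0024), 13 on both arrays and 2 higher on both, with the fucosyltransferase Fut2 at -0.55 ± 0.11, the acute phase gene Saa2 at -0.52 ± 0.27, the cytokine Il18 at -0.38 ± 0.07 and the mucin Muc13 at -0.24 ± 0.09. Paneth cell markers were lower (9 genes, 4 lower and 1 higher on both arrays and 4 opposite ways, median -0.23, camera adjusted p = 0.000221), with lysozyme Lyz1 at -0.50 ± 0.40, Itln1 at -0.34 ± 0.42, Pla2g2a at -0.25 ± 0.15 and Ang4 at -0.23 ± 0.20. Lists of tissues outside the gut wall had lower medians too, with many members going opposite ways on the arrays. The exocrine pancreas list (17 genes, 4 lower on both arrays and 13 opposite ways, median -0.09, camera adjusted p = 0.0029) had Pnliprp1 at -0.46 ± 0.04, and the red blood cell list (7 genes, 2 lower on both and 5 opposite ways, median -0.29, camera adjusted p = 0.0025) had Hba-a2 at -0.35 ± 0.17. The adipocyte list (13 genes, 6 lower on both and 6 opposite ways, median -0.05, camera adjusted p = 0.0251) had adipsin, Cfd, at -0.50 ± 0.03, and the hepatocyte list (10 genes, 6 lower and 2 higher on both, median -0.06, camera adjusted p = 0.0322) had Tat first and Cyp2e1 at -0.44 ± 0.06, while Cps1 was at 0.17 ± 0.10. With the outlier spots kept in the background fit, 4 of these lists did not pass camera: Paneth cells (median 0.00, adjusted p = 0.792), drug metabolism (median -0.04, adjusted p = 0.0867), exocrine pancreas (median -0.08, adjusted p = 0.1735) and hepatocytes (median -0.02, adjusted p = 0.1735). With the processed ratios, adipocytes did not pass camera (adjusted p = 0.152), at a median of -0.10. With an estimated correlation, the adjusted p of all of them was 0.605, and 0.677 for adipocytes.

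The region of the gut and its epithelial types were looked at through markers. Proximal small intestine genes were higher (15 genes, median 0.07, camera adjusted p = 0.0073, adjusted p = 0.605 with an estimated correlation), led by Lct and Fabp1, with the hormone Gip at 0.44 ± 0.16 and Ces2c at 0.29 ± 0.19. Distal small intestine genes had a median of -0.07 (16 genes, adjusted p = 0.053), with the hormone Fgf15 at -0.49 ± 0.23. This list passed camera downward in 4 alternatives (adjusted p = 0.0041 with median centring, 0.0332 with the mean of probes, 0.0357 with a surface removed and 0.0439 without the filter on dim probes). Respiratory chain genes had a median of 0.02 (32 genes, adjusted p = 0.048, adjusted p = 0.605 with an estimated correlation), with Uqcrfs1 at 0.30 ± 0.04 and Ndufv2 at 0.26 ± 0.04. This list did not pass camera with the processed ratios (adjusted p = 0.456) or the deposited value table (0.4532). Nor did it pass with normexp offset 0 (0.2355), no background correction (0.0643) or median centring (0.5253), where its median was -0.05. The antimicrobial Reg list had a median of -0.10 (10 genes, camera adjusted p = 0.0614), with Reg1 at -0.28 ± 0.05, Reg3a at -0.25 ± 0.01 and Reg4 at -0.25 ± 0.02. This list passed camera downward in 7 alternatives, with adjusted p from 0.0223 with the mean of probes to 0.0433 with a surface removed, and at 0.0229 with the processed ratios (median -0.22). Absorptive enterocyte markers had a median of -0.01 (adjusted p = 0.599), goblet cell markers 0.04 (adjusted p = 0.431), enteroendocrine markers 0.00 (adjusted p = 0.907), and stem and proliferation genes 0.02 (adjusted p = 0.457). Colon markers had a median of -0.01 (adjusted p = 0.346), smooth muscle 0.00 (adjusted p = 0.566), fibroblasts and endothelium -0.03 (adjusted p = 0.566), and enteric neurons and glia -0.08 (adjusted p = 0.115). With the outlier spots kept, camera called absorptive enterocyte (median 0.11, adjusted p = 0.0013) and goblet cell markers (0.17, adjusted p = 0.0016) upward and enteric neurons and glia downward (-0.11, adjusted p = 0.0154).

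The other metabolic and stress lists did not pass camera. Medians were -0.04 for fatty acid synthesis (adjusted p = 0.0793), -0.03 for fatty acid oxidation (adjusted p = 0.746), -0.02 for bile acid carriers (adjusted p = 0.388), -0.08 for sugar digestion and transport (adjusted p = 0.108) and -0.04 for peptide and amino acid transport (adjusted p = 0.487). They were 0.01 for antioxidant genes (adjusted p = 0.994), -0.02 for the unfolded protein response (adjusted p = 0.346), -0.03 for the circadian clock (adjusted p = 0.566), -0.05 for immediate early and heat shock genes (adjusted p = 0.796) and 0.00 for cytosolic ribosomal proteins (adjusted p = 0.917). Some passed in alternatives: with the outlier spots kept, ribosomal proteins (median 0.18, adjusted p = 4.49e-08) and antioxidant genes (adjusted p = 0.0296) upward. With median centring, camera called fatty acid synthesis (adjusted p = 0.0278), sugar digestion (adjusted p = 0.0383) and the unfolded protein response (adjusted p = 0.0417) downward. Without the filter on dim probes it called sugar digestion (adjusted p = 0.037) downward. Single members on the same side on both arrays included Acot12 at 0.56 ± 0.07, G6pc at -0.53 ± 0.14 and the fructose carrier Slc2a5 at -0.31 ± 0.02. In total 17 of the 39 lists passed with the preset correlation, 8 upward and 9 downward, and none with an estimated one, which rests on 1 residual degree of freedom. The split was 13 upward and 4 downward with the outlier spots kept, and 6 and 14 with median centring in place of loess. No member of any list passed limma over all genes tested, and 16 list memberships passed when adjusted over the list alone, with Fabp1 counted in both of its lists. The median and the mean or test of a list differed in sign for fatty acid oxidation, sugar digestion, antioxidant, ribosomal protein and absorptive enterocyte genes.

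**Figure D3:**
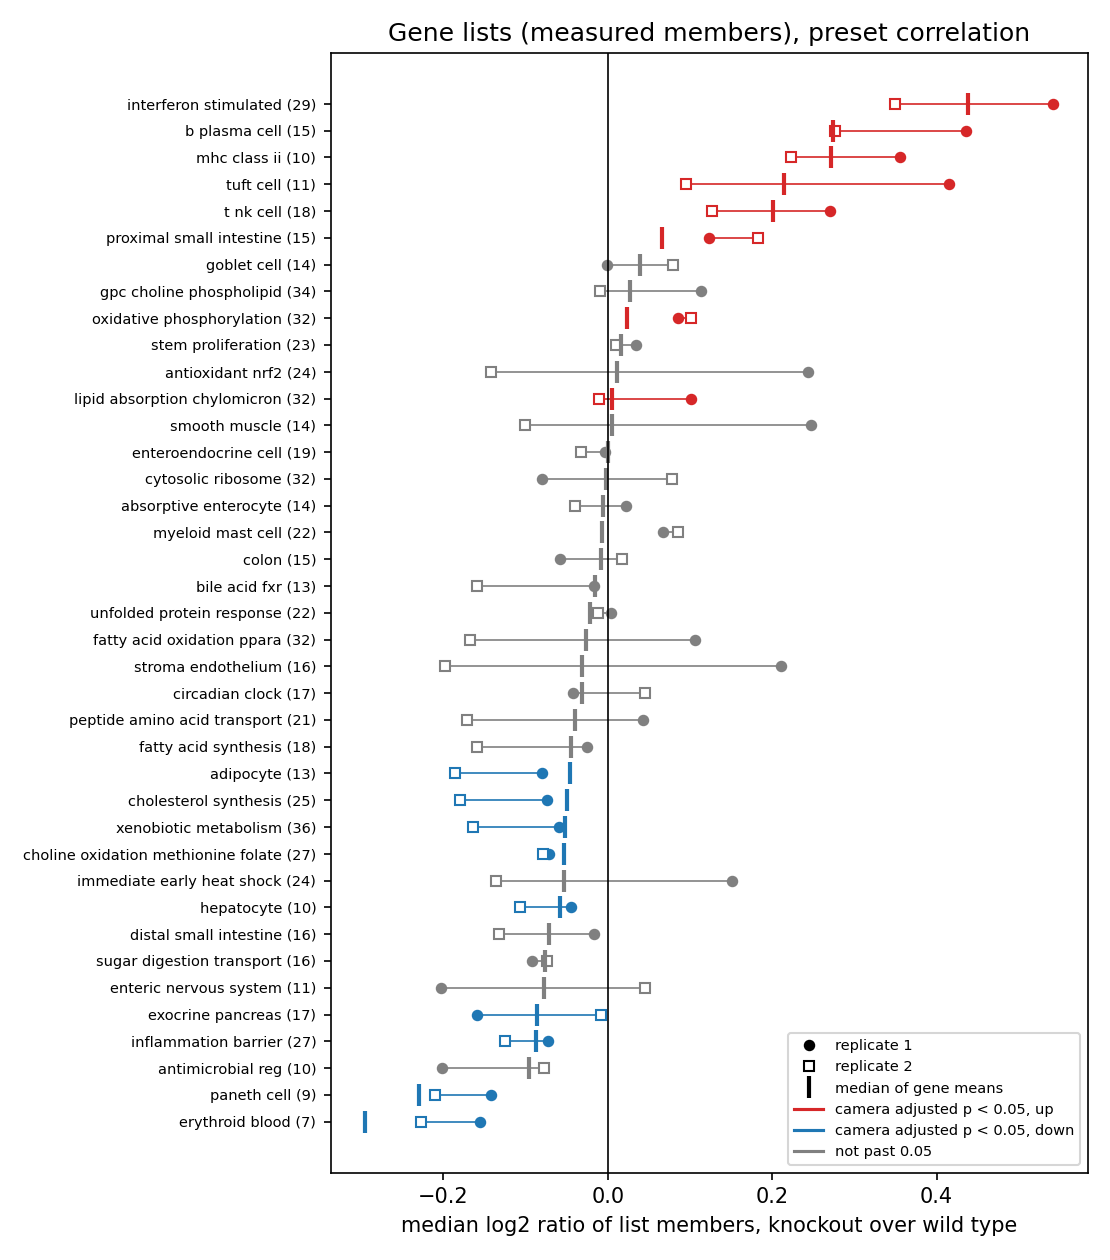
Median log2 ratio of the RNA labelled knockout over the RNA labelled wild type (horizontal axis) for 39 gene lists, with the number of measured members in brackets. Circles are replicate 1, squares replicate 2, and vertical marks the median of the members' means; red and blue mark lists past a camera adjusted p of 0.05 with the preset correlation, upward or downward, with the interferon list at 0.44 and the red blood cell list at -0.29.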

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

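The spike-in control spots, which carry adenovirus E1A sequences meant for RNA added during labelling, were not used in any comparison. Of their spot readings over both arrays, 23.4% were well above background in at least 1 channel, against 0.654% for the negative control spots. The signal was low, with background-subtracted medians of the 10 spike-in probes between -1.46 and 20.5 per channel and array. No group of samples was large enough to test for single outlying samples.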

How the results depend on the processing

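Keeping outlier spots in the background fit, and taking off a surface over row and column, were chosen after the data were seen. No gene passed limma with no background correction, median centring, Aquantile, other filters, mean probes, robust eBayes, outlier spots kept or an adjusted p under 0.1, but 22 passed with normexp offset 0, 38 with processed ratios, 36 with the deposited value table, 6 with the surface removed and 2 with an intensity trend in eBayes; the error-model p took 122 genes, against 56 in the same dye direction. The count of 41 genes at least 1.5-fold apart became 89 with offset 0, 159 with processed ratios, 157 with the value table, 21 with outlier spots kept, 8 at 2-fold and 141 at 1.3-fold, and 756 to 1049 on 1 array alone; it lay between 31 and 50 elsewhere. The cause was not tested, beyond the thresholds and arrays left out. All 22 genes of the size rule named in the text kept their direction wherever measured, and 17 of the 41 genes remained with outlier spots kept. Gpcpd1 stayed above 0 in every alternative, from 0.28 to 1.08 on single arrays, at 0.41 as the mean of its probes, and uncalled. Between 13 and 20 lists passed in the alternatives with the preset correlation, 16 by percentile and 0 with an estimated correlation. The 16 were not all among the 17 of camera. Lipid absorption (percentile 78.12), respiratory chain (94.775), sterol (3.415), adipocyte (11.32) and hepatocyte lists (4.72) passed camera but lay inside the middle 95% of matched random lists. Sugar digestion (0.64), immediate early (1.9), Reg (0.4) and distal lists (0.38) lay outside it but did not pass camera in the main fit. With outlier spots kept, 11 of the 17 lists still passed and 17 passed in all, 13 upward and 4 downward; with median centring the split was 6 and 14. The 199 genes apart in a dye direction became 111 with processed ratios, 997 with median centring and 30 with the surface removed. Interferon, B cell, T cell, MHC class II, tuft, proximal, inflammation and red blood cell lists kept their call in all processing alternatives except that correlation. Lipid absorption had a median of -0.0106 without replicate 1 and 0.1009 without replicate 2, and antioxidant genes passed upward at 0.0828 with outlier spots kept. Median centring moved the median of all genes to 0.08 in replicate 1 and -0.13 in replicate 2. Tests without a replicate could not be run, since 1 array leaves no spread. The test of ratios against 0 pairs the genotypes within each array, and no further pairing was possible because both arrays belong to 1 group of ratios. Signal over background limits dim genes, whose ratios the offset pulls towards 0: Svs5 was at -1.03 with offset 50 and -2.61 with offset 0. Kap was at 1.42 with offset 50 and 2.11 with offset 0.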

Other observations

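The clone AK090125, described in the files as a melanoma antigen, was the transcript furthest apart in the intestine, 11.4-fold higher in the RNA labelled knockout (3.52 ± 0.37, chromosome 8, 125949940 to 125949999, mm9). Mt1 was lower while Mt2, its neighbour among the metallothioneins, was at -0.13 ± 0.37, and Slc30a1, a zinc exporter also induced by zinc, was at -0.22 ± 0.53, with a second probe at -0.53 ± 0.09. Svs4 was, like Svs5, not well above background in the RNA labelled knockout and at least 1.23-fold lower. Among the 41 genes at least 1.5-fold apart on both arrays, 4 immunoglobulin segments were higher and 1 was lower. Ckm and Acta1, both abundant in skeletal muscle, were at -0.07 ± 0.08 and -0.07 ± 0.09. Pvalb, a calcium buffer of fast fibres, was not well above background in the RNA labelled wild type. It was at least 1.44-fold higher in the RNA labelled knockout, and 10.8-fold higher with processed ratios. Other muscle genes were higher on both arrays too, with Tnnt3 and Myh1 at 0.78 ± 0.08 and 0.78 ± 0.06. Xirp2 was at 0.34 ± 0.01, Myoz1 at 0.33 ± 0.06, Mb at 0.28 ± 0.06 and Actn3 at 0.26 ± 0.02. With processed ratios these genes lay between 1.33 for Actn3 and 3.07 for Myh1, and limma called each. A list of 11 kidney genes, chosen after Kap was seen, had a median of -0.04.

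Of the tests below, both on Gpcpd1 and the muscle genes with Myh4, Myh8, Tnnc2 and Tnni2 put back were chosen after the values had been seen; the others were fixed before their values were seen, on patterns already noticed. Gpcpd1 was not lower in the RNA labelled knockout. A dye bias of its probes would turn their sign with the dyes, but 3 of 4 probes were higher on both arrays. Probe A_52_P384069 lay at 0.62 with an SD of 0.08, a size that 0.31% of the 29046 tested probes reached. It was picked as the one of the 4 that exceeded its SD most, so this share overstates how rare it is. The brightest probe, A_52_P470017, was less even, at 0.28 and 1.08, and at 0.02 and 1.23 with processed ratios. Reversed labels on both arrays would raise the probes inside the deleted part and need not raise the others. Which probes lie inside is not known here, so the lowest probe, A_52_P407755, at -0.13 with an SD of 0.43, decides nothing. Reversed labels and transcript left outside the deleted part cannot be told apart here, and the second was not tested.

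Several skeletal muscle genes, among them Myh4, Myh8, Tnnc2 and Tnni2, were higher in the RNA labelled knockout. For a larger share of the gut's own smooth muscle, the bound set beforehand was a list median of 0.58. This is the 1.5-fold of the size rule, not a value worked out for a mixture of tissues. The median was 0.0048 with a quartile range over 2 of 0.07, which argues against a rise of that size. A smaller rise was not tested by this bound. For muscle tissue carried over with the samples, the same bound was set for other skeletal muscle genes. The 21 taken, 11 higher and 3 lower on both arrays, missed it. Their median was 0.18 with a quartile range over 2 of 0.14 (0.24 and 0.32 with processed ratios). The miss does not decide whether muscle was carried over, since the offset pulls dim genes towards 0. The list also leaves out Myh1, Tnnt3, Pvalb, Xirp2, Myoz1, Mb and Actn3. These were higher on both arrays, and limma called them with processed ratios. Apart from Tnnt3, none of them was well above background in the RNA labelled wild type on both arrays. With Myh4, Myh8, Tnnc2 and Tnni2 put back, a set partly picked for being higher, the median was 0.22. With processed ratios it was 0.54 with a quartile range over 2 of 0.30, so that the bound lay within this spread. The other genes left out stayed out here too. The 21 genes lay at the 100th percentile of matched random lists. Muscle carried over with the samples stays open, as does a change of these genes in the gut itself, which was not tested.

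Fabp1, Lct and Plb1 were higher in the RNA labelled knockout. For a larger share of absorptive enterocytes, the bound set beforehand was a list median of 0.58, again that of the size rule. The median was -0.0054 with a quartile range over 2 of 0.06, and 0.11 with outlier spots kept. A rise of that size was thus not seen. Since loess centres the bulk of genes at 0, a cell type that supplies much of the RNA could shift less. The bound therefore does not decide on a smaller rise. A more proximal stretch of gut could raise Fabp1 and Lct: without them, the proximal list had a median of 0.0363, at the 92.5th percentile of matched random lists, and the distal list a median of -0.07, at the 0.38th. The proximal value missed the 95% set beforehand and did not fall below 0. With outlier spots kept, the proximal list lay at the 96.35th percentile and the distal list at the 2.19th, though the distal median was 0.01. With processed ratios, the proximal median was 0.0019 at percentile 74.53 and the distal median -0.06 at percentile 7.5. Position along the gut therefore stays open, as does an effect of the genotype, which was not tested apart from it.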
